A study of Mus musculus with 8 samples.

How the data were processed

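RNA of mouse pancreatic buds was measured on Affymetrix mouse gene 1.0 ST arrays, with 8 arrays in all. The submitters' labels put them in 4 groups: VEGF buds (Pdx1-tTA with TET-VEGF), control littermate buds (Pdx1-tTA), explants with VEGFR2i and explants with vehicle. Per the labels, each group is 1 pool of RNA, from 3 embryos for the fresh buds and from 5 for the explants, hybridized once and then again as a technical repeat. Groups were taken from the labels alone and were kept as labelled throughout, including the explant pools whose endothelial genes go against the labels. Whether the buds of a pool came from 1 litter, and which sex they had, is not given in the sources used here. RNA was isolated with a QIAGEN micro kit and labelled by the Affymetrix whole transcript protocol, per the labels' protocols.

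The deposited values are log2 expression per probe set, normalized by the authors by robust multi-array averaging (RMA) in Partek Genomic Suite 6.5, per the series' design text. The log2 scale was read from the values, which run from 2.41 to 13.57. RMA corrects background, sets the arrays of a run to 1 distribution and summarises probes, which can hide a change shared by most genes and compresses differences of dim genes. The bud arrays had medians of 4.08, 4.10, 4.12 and 4.10 and the explant arrays 4.29, 4.33, 4.33 and 4.32. Differences in shape remained between the sets. RMA sets the distribution before probes are summarised, so such differences do not settle how the sets were normalized. Separate normalization of the sets is possible. Comparisons were therefore made within a set, and levels across sets are named as such. The design text also states that the authors picked genes by p-values and ratios with a t-test; their thresholds and gene table were not used here.

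Probe sets were named through the platform annotation. Of 35399 probe sets, 21789 had exactly 1 gene symbol, 1621 had several and 11989 were not listed there and stayed unnamed. Entrez IDs of 21698 singly named probe sets matched a RefSeq gene table of the assembly GRCm38.p6, used for names only, and no symbol needed updating. No gene was named from a probe set with several symbols. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays stood for the gene, which left 19938 genes. The precision of the values is limited by the number of arrays, which is 2 per pool.

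With 1 pool per group no test of the conditions was possible, so genes were selected by size. A gene counted as higher or lower when the means of the pools differed by at least 1.5-fold and both arrays of one pool lay above both of the other. The second part of the rule removed no gene. As a measure of technical error, the same size was counted between the 2 arrays of each pool. A p-value over arrays of the same pools measures hybridization error, not the conditions. Under that limit the methods' t-test on the arrays, with 1.5-fold, gave 271 genes for VEGF over control and 405 for the explants without adjustment for multiple tests, and 0 and 1 after Benjamini-Hochberg adjustment. The linear model of limma on all 8 arrays gave 294 and 435 at an adjusted p under 0.05 with 1.5-fold.

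The groups, the rule of size, the alternatives, the rule for named genes and 23 gene lists were fixed before the data were examined. Named genes were, per comparison, Vegfa, Kdr and Pdx1, the 12 genes with the largest increase and the 12 with the largest decrease among those past the size rule, up to 4 members per list with the largest absolute difference, and up to 6 genes per pair of opposite directions between the comparisons. Symbols of predicted genes and of large receptor clusters were left out of the named genes but not of the counts. Apoa1, Apoa2, Afp, Cdh1, Cpa1, Gcg, Lrrn4 and Unc5b in the buds, Gcg, Ins2 and Neurog3 in the explants, and some genes shared by both comparisons fall outside that rule and were picked after their values were seen. The lists covered endothelial cells, VEGF-responsive tip cell genes, mural cells, erythroid cells, macrophages and other leukocytes, acinar enzymes and secretory proteins, acinar and tip transcription factors, endocrine progenitors, islet hormones and granule genes, progenitor transcription factors, epithelium and duct, mesenchyme, cell cycle, hypoxia and glycolysis, the Notch pathway, basement membrane, neural crest with glia and neurons, liver, a list of stomach, intestine and spleen, mesothelium, immediate early genes, p53 and unfolded protein stress, and sex-linked genes. Of their 466 members, 435 were measured and 31 had no singly named probe set and were not analysed here. Lists share some members, such as Kdr and Flt1 in the endothelial and tip cell lists. A list was described by its median difference and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these pools and is no test of a condition. A further 4 lists were written for the closing section after the main values had been seen: liver-secreted proteins, megakaryocytes and platelets, arterial endothelium, and venous and lymphatic endothelium.

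The size rule was tested on simulated data for VEGF over control with 19938 genes, of which 200 were changed. It recovered 99 of 200 genes changed by exactly 1.5-fold, 200 of 200 at 2-fold and 200 of 200 at 3-fold, with 2, 5 and 2 false calls. The simulation used technical error alone. It gave dim genes the full change, without the compression of real dim genes, so it can overstate recovery among them. Alternatives covered other sizes, run-matched array pairs, array-level tests, a filter on dim genes, quantile normalization of all 8 arrays, centring on array medians, the mean of a gene's probe sets, all probe sets, and each array left out in turn. Quantile normalization was added for the endothelial level of the explants against fresh buds after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1. No genome coordinates are given, since the values carry none.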

Results

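Gene expression was measured in mouse pancreatic buds from embryos at e12.5, the stage at which the early pancreatic epithelium branches within its mesenchyme. A first pair of RNA pools came from freshly isolated buds. The VEGF pool held buds of 3 embryos carrying both Pdx1-tTA, which places the tetracycline transactivator under the promoter of the pancreatic factor Pdx1, and TET-VEGF, a VEGF transgene that this transactivator switches on. The control pool held buds of 3 littermates carrying Pdx1-tTA alone. A second pair of pools came from wild-type buds explanted at e12.5 and kept in culture for 2 days with an inhibitor of VEGF receptor 2, called VEGFR2i in the labels, or with vehicle, 5 in each pool. Each pool was hybridized to 2 arrays, a first array and a technical repeat, which gave 8 arrays of 35399 probe sets. Each condition was thus 1 pool of RNA with no biological replicate, and the SDs printed here (n = 2 arrays) measure technical error only. Expression is on the log2 scale, and differences are between pool means, followed in brackets by the range over the 4 pairs of arrays.

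The arrays of a pool were nearly identical, with a correlation across probe sets of 0.997 to 0.998. It was 0.996 between VEGF and control arrays and 0.995 to 0.996 between VEGFR2i and vehicle arrays. A gene was counted as higher or lower when the pool means differed by at least 1.5-fold (0.58 on the log2 scale) and both arrays of one pool lay above both arrays of the other. Between the 2 arrays of a single pool, 10 of 19938 genes differed by that size in the VEGF pool, 6 in the control pool, 25 in the VEGFR2i pool and 4 in the vehicle pool. Array medians lay between 4.08 and 4.12 for the fresh buds and between 4.29 and 4.33 for the explants.

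The first comparison asked what added VEGF in the Pdx1 territory did to gene expression in the bud. Endothelial genes and red blood cell genes were higher in the VEGF pool than in the control pool, and genes of endocrine differentiation were lower. Esm1, a VEGF-induced gene of endothelial tip cells, was higher by 1.75 [1.65, 1.86], or 3.37-fold, at 5.44 ± 0.13 (SD) against 3.69 ± 0.02. Neurog3, the transcription factor that commits progenitors to the endocrine lineage, had the largest decrease of the genes named in this comparison, with a difference of -2.63 [-2.87, -2.39] and levels of 4.45 ± 0.26 against 7.08 ± 0.08. Chga, a protein of endocrine secretory granules, was lower by a difference of -1.76 [-1.81, -1.71], at 5.87 against 7.63. The digestive enzyme precursor Ctrb1 differed by -2.07 [-2.11, -2.03], at 6.15 against 8.22.

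Of 34 endothelial genes, 11 were higher by the size rule and none was lower. The list's median difference was 0.51, a 1.42-fold level, and lay above those of all 10000 random lists matched on expression (percentile 100). Positive differences were seen for 33 of the 34 members. Cd34 differed by 1.02, the lymphatic and early vascular receptor Flt4 by 0.92, Adgrl4 by 0.91 and the VEGF receptor Flt1 by 0.90. Kdr, the gene of VEGF receptor 2, was higher by 0.75 [0.70, 0.80], at 9.49 against 8.74. Among 18 genes of VEGF-responsive tip cells, 5 were higher, including Esm1, Hlx (0.66) and Unc5b (0.60), with a list median of 0.16 at percentile 100 and a mean of 0.34. Flt1 and Kdr completed the 5 and are also in the endothelial list, while Hlx is also in the mesenchyme list. The 13 members short of the size rule included Nid2 (0.38), Dll4 (0.14), Angpt2 (0.06) and Apln (0.05). Vegfa itself differed by 0.27 [0.06, 0.48], at 7.70 ± 0.04 against 7.43 ± 0.26, and did not reach the size rule. Whether its probe set lies within the part of Vegfa carried by the transgene is not given in the sources used here, so this value is no check of the genotype.

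Of 15 erythroid genes, 7 were higher and none lower, with a list median of 0.44 at percentile 100. The embryonic globin Hbb-bh1 differed by 1.72 [1.70, 1.74], the anion exchanger of red cells Slc4a1 by 1.37, Rhag by 1.13, Kel by 1.03 and the haem synthesis enzyme Alas2 by 1.01. The platelet chemokine Ppbp had the largest increase of the genes named in this comparison, 2.47 [2.23, 2.70] or 5.53-fold, followed by the plasma protein gene Alb with 2.37 [2.25, 2.49] or 5.16-fold. Of 15 genes of the liver list, Alb, Apoa1 (0.74), Afp (0.72) and Apoa2 (0.70) were higher while Rbp4 (-1.23), Ttr (-1.11) and Ambp (-0.81) were lower, leaving the median at 0.04 (percentile 91.6). In the control pool Rbp4, Ttr and Ambp were at 9.44, 10.7 and 10.1, against 4.73 for Alb and 8.28 for Afp. Those lower members therefore need not report liver tissue. Leukocyte genes did not move with the red cell genes: none of 20 reached the size rule, and their median was 0.03 (percentile 81.3). Genes of mural cells, which wrap vessels, had 1 member higher (Mcam, 0.59) and 1 lower (Anpep, -0.77) of 14, and a median of 0.05 (percentile 93.8). Among 16 basement membrane genes, Lama4 (0.67) and Col4a2 (0.62) were higher, and the median was 0.14 (percentile 99.99).

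Endocrine genes were among those lower, in both lists that describe them. Of 26 genes of islet hormones and secretory granules, 14 were lower and none higher, with 25 of 26 differences negative and a median of -0.62 (percentile 0.00). Scg3 had the largest decrease of that list (-1.85), followed by Chga, Chgb (-1.65) and the gut and islet peptide Pyy (-1.52), and the glucagon gene Gcg was at 10.7 against 12.1, a difference of -1.37. Of 19 endocrine progenitor genes, 8 were lower and none higher, with a median of -0.36 (percentile 0.00). After Neurog3 the largest differences of that list were those of Rfx6 (-1.79), Neurod1 (-1.58) and Pax6 (-1.27), all transcription factors of the endocrine lineage. Of 28 genes of acinar enzymes and secretory proteins, 5 were lower, namely Ctrb1, Clps (-1.87), Pnliprp1 (-1.72), Cel (-0.89) and Cpa1 (-0.87), and none was higher. Many other members of that list were at the dim end of the range in both pools, the median levels being 3.51 and 3.57. Its median difference was -0.06 (percentile 0.590) and became 0.00 without VEGF array 1, while its mean was -0.33. None of 7 acinar and tip transcription factors reached the size rule, and their median was -0.07 (percentile 7.05). In that group Nr5a2 differed by -0.54 and Ptf1a, at a level near 3.9 in both pools, by -0.08.

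Part of the genes of the pancreatic epithelium were lower as well. Of 26 epithelial and duct genes, 10 were lower and 1 was higher, with a median of -0.51 (percentile 0.00). The mucin Muc1 (-1.005), the splicing factor Esrp1 (-0.78), the tight junction protein Cldn7 (-0.73) and E-cadherin, Cdh1 (-0.64), were among those lower, and the member that was higher was the carbonic anhydrase Car2 (1.37), which red cells also express. Of 17 progenitor transcription factors, 5 were lower and none higher, with a median of -0.41 (percentile 0.00), led by Nkx6-1 (-0.94), Prox1 (-0.72), Hnf4a (-0.71) and Sox9 (-0.70). Pdx1, whose promoter drives the transactivator in both pools, differed by -0.58 [-0.76, -0.40], at 6.38 against 6.96, just short of the size rule. Outside these lists, the amino acid transporter chaperone Cltrn (-2.21) and the transporter Slc38a5 (-1.65), a gene of the developing pancreas, were among the largest decreases. So was Cck (-1.65). Oit3 (1.35, at 6.15 against 4.79) and Lhx9 (1.18, at 6.09 against 4.90), which are in no list, were among the largest increases.

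Mesothelial genes, which mark the lining of the organ surface, were higher: 5 of 10 passed the size rule, Gpm6a (0.95), Upk1b (0.86), Bnc1 (0.76), Upk3b (0.73) and Lrrn4 (0.59), and the median was 0.47 (percentile 100). Of 26 mesenchymal genes, Hlx (0.66) was higher, Prrx1 (-0.77) and Osr1 (-0.61) were lower, and the median was 0.10 (percentile 100). The 29 cell cycle genes had a median of 0.11 (percentile 100) with no member past the size rule. Of 16 genes of neural crest, glia and neurons, Ret (-0.84), Stmn2 (-0.81) and Erbb3 (-0.79) were lower, and the median was -0.10 (percentile 0.230), or 0.01 without VEGF array 1. Hypoxia and glycolysis genes had 1 of 28 members lower, Ndrg1 (-0.82), and a median of 0.05 (percentile 95.9). No member passed the size rule among 20 Notch pathway genes (median 0.01, percentile 65.5), 15 genes of stomach, intestine and spleen (0.04, percentile 92.1), 16 immediate early genes (0.07, percentile 96.5) or 16 genes of p53 and unfolded protein stress (0.04, percentile 88.1). The median of 4 sex-linked genes was 0.51 (percentile 99.99): the Y-linked Kdm5d was higher by 0.72, Eif2s3y differed by 0.54 and Uty by 0.47, and Xist, which is expressed from the inactive X chromosome, differed by -0.45.

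In all, 296 of 19938 genes met the size rule between the VEGF and control pools, 110 higher and 186 lower, with a median difference over all genes of 0.00. With 1 pool per condition these counts compare 2 pools of RNA, and no p-value for the transgene can be had. Differences in embryo number of each sex, in stage or in dissection between the pools are part of the same values.

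**Figure D1:**
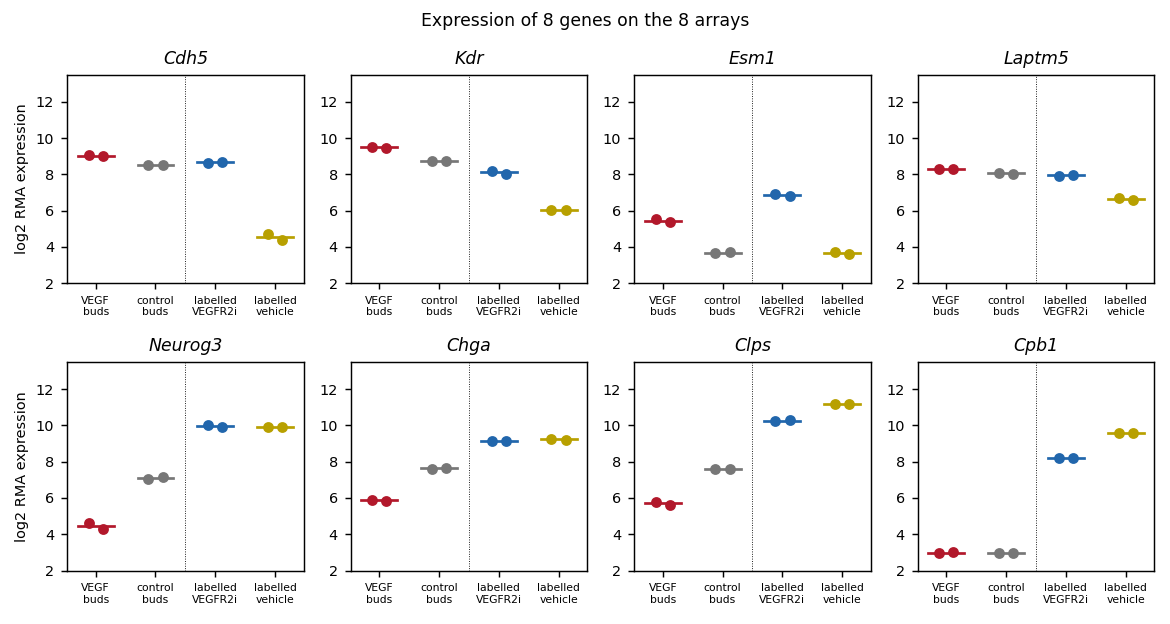
Expression on each of the 8 arrays (points; y axis, log2 RMA expression) by pool (x axis), with a line at the pool mean, for 8 genes of endothelium, leukocytes, endocrine cells and acinar cells. Neurog3 and Chga were lower in the VEGF pool than in the control pool (differences of -2.63 and -1.76), and Cdh5 was higher in the pool labelled VEGFR2i, at 8.66, than in the pool labelled vehicle, at 4.56.

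The second comparison asked what blocking VEGF receptor 2 for 2 days did to explanted buds. Its direction goes against its labels: an inhibitor of the receptor that endothelial cells depend on should lower their genes, and endothelial genes were many times higher in the pool labelled VEGFR2i. Cdh5, the cadherin of endothelial junctions, differed by 4.097 [3.92, 4.27], or 17.1-fold, at 8.66 ± 0.02 in the pool labelled VEGFR2i and 4.56 ± 0.23 in the pool labelled vehicle. Pecam1 differed by 3.39, at 7.70 against 4.31, and Kdr, the receptor's own gene, by 2.10 [2.00, 2.19], at 8.12 against 6.02. Digestive enzyme genes went the other way, with Cpb1 at 8.21 against 9.59 in the pool labelled vehicle, a difference of -1.38 [-1.39, -1.38], and Sycn, a protein of zymogen granules, at 7.33 against 8.81, a difference of -1.48 [-1.54, -1.43]. Every direction given for the explants follows the labels as they stand.

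Of 34 endothelial genes, 29 were higher in the pool labelled VEGFR2i, all 34 differences were positive, and the median was 1.63, a 3.10-fold level (percentile 100). Cd93 (3.96, or 15.6-fold), Emcn (3.14), Tie1 (3.05) and the arterial connexin Gja5 (3.12) were among the largest differences between the explant pools. Of the 18 VEGF-responsive tip cell genes, 9 were higher, led by Esm1 with 3.19 (6.84 against 3.66), Cxcr4 with 2.53 and Flt1 with 2.31, and the median was 0.60 (percentile 100) and the mean 0.96. Mural cell genes were higher too, 9 of 14, with a median of 0.72 (percentile 100), including Rgs5 (1.26), Pdgfrb (1.15), Abcc9 (1.07) and Cspg4 (0.88). Leukocyte genes had 13 of 20 members higher and a median of 0.77 (percentile 100), with Laptm5 at 1.35, Cybb at 1.31, Mrc1 at 1.28 and the macrophage receptor Adgre1 at 1.09. Of 15 erythroid genes only the globins Hbb-y (2.23) and Hba-x (1.62) were higher, and the median was 0.00 (percentile 75.6). Many other erythroid members were at the dim end of the range in both explant pools, with median levels of 3.36 and 3.40. The erythroid median therefore says little about red cells there. Of 20 Notch pathway genes, 7 were higher, among them Hey1 (1.502), the endothelial ligand Dll4 (1.44), Notch4 (1.09) and Hey2 (0.80), with a median of 0.22 (percentile 100). Among 16 basement membrane genes, Lama4 (1.23), Col4a2 (1.04), Col4a1 (0.89) and Nid1 (0.76) were higher, and the median was 0.20 (percentile 100). Vegfa was at 8.10 in the pool labelled VEGFR2i and 8.14 in the pool labelled vehicle.

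Of 28 acinar enzyme and secretory genes, 15 were lower in the pool labelled VEGFR2i and none higher, 27 of 28 differences were negative, and the median was -0.63 (percentile 0.00). After Sycn and Cpb1, the largest differences were those of Rnase1 (-1.32) and the elastase Cela3b (-1.22), while the trypsin gene Try10 differed by -1.21, and the colipase gene Clps by -0.91 (10.3 against 11.2). Trypsins and elastases are families of related genes, some of them close copies, so single members can be uncertain. The acinar and tip transcription factors had 2 of 7 members lower, Bhlha15 (-0.95) and Rbpjl (-0.72), and a median of -0.52 (percentile 0.00). Ptf1a, with a difference of -0.58, and Gata4, with -0.52, lay just under the size rule. Endocrine genes differed less. Of 26 islet genes, Slc30a8 (-0.70) and G6pc2 (-0.61) were lower, with a median of -0.17 (percentile 0.00), and Ins2 differed by -0.33 and Gcg by -0.15. Endocrine progenitor genes had 1 of 19 members higher, Mfng (0.76), which is also in the Notch list, and a median of -0.01 (percentile 18.7), with Neurog3 at a difference of 0.06. Progenitor transcription factors had no member past the size rule and a median of -0.10 (percentile 0.150), and Pdx1 was at 8.43 in both pools. None of 26 epithelial and duct genes passed the size rule, though 25 differences were negative and the median was -0.21 (percentile 0.00).

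Of 26 mesenchymal genes, 5 were higher, among them Thy1 (1.23), Postn (0.75), Hlx (0.69) and Zeb1 (0.68), with a median of 0.19 (percentile 100). Immediate early genes had 3 of 16 members higher, Egr2 (1.04), Egr1 (0.67) and Dusp1 (0.66), and a median of 0.14 (percentile 99.9). Hypoxia genes had 1 of 28 higher, Stc1 (0.94), with a median near 0.00 (percentile 25.04), the neural list had 1 of 16 higher, Fabp7 (0.74), with a median of -0.06 (percentile 10.8), and the stomach, intestine and spleen list had 1 of 15 higher, Tlx1 (0.95), with a median of -0.08 (percentile 3.96). No member passed the size rule among cell cycle genes (median 0.02, percentile 29.1), liver genes (-0.04, percentile 15.7), mesothelial genes (0.09, percentile 95.0), genes of p53 and unfolded protein stress (-0.01, percentile 29.8) or sex-linked genes (-0.08, percentile 11.6). Altogether 437 genes met the size rule, 363 higher and 74 lower in the pool labelled VEGFR2i, again as a comparison of 1 pool with 1 pool. Since the endothelial genes go against the labels, none of these directions can be read as an effect of the inhibitor.

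**Figure D2:**
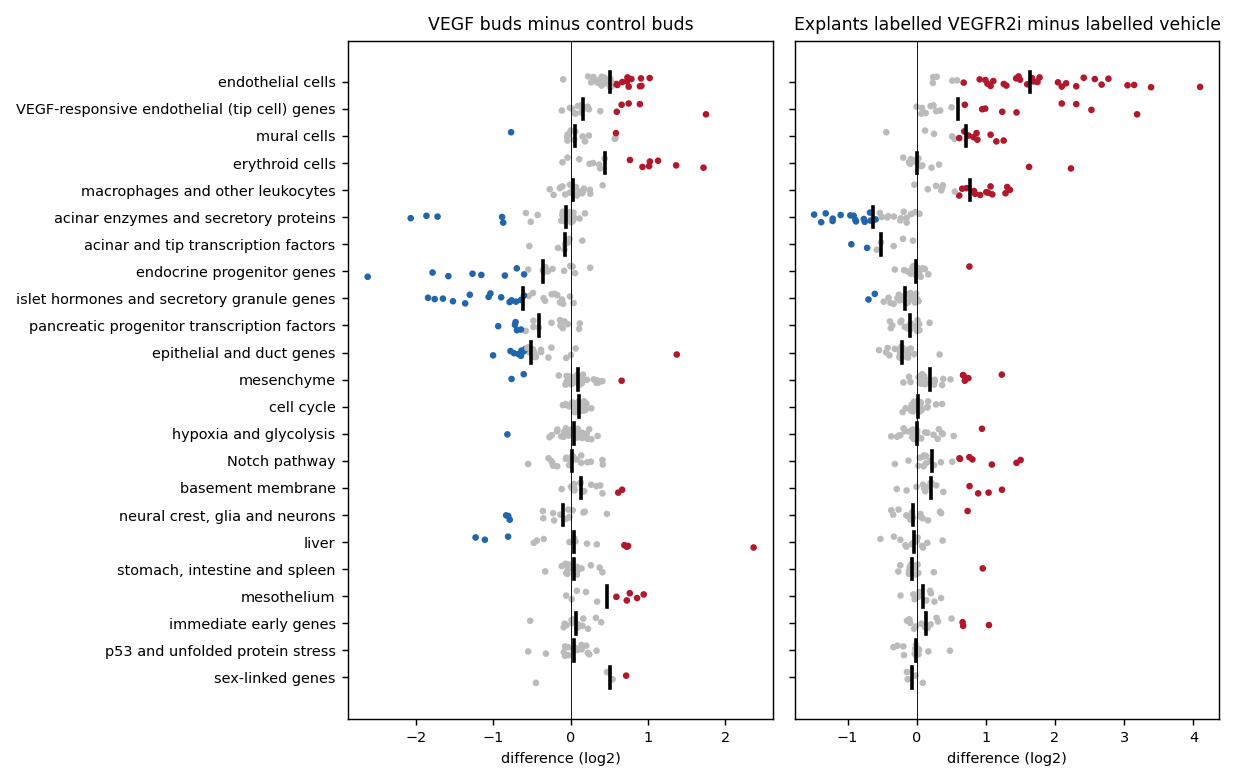
Differences in log2 expression (x axis) of the members of 23 gene lists (y axis), left for VEGF over control and right for the pool labelled VEGFR2i over the pool labelled vehicle; red dots are members higher by the size rule, blue dots members lower, grey dots neither, and the black bar is the list median. The endothelial medians were 0.51 and 1.63, the islet medians -0.62 and -0.17, and the acinar enzyme medians -0.06 and -0.63.

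Levels were also set across the fresh buds and the explants. The array medians of the vehicle pool lay 0.21 above those of the control buds, and the sets may have been normalized separately. Acinar enzyme genes lay above the control buds by a median of 3.59 in the pool labelled vehicle and 2.63 in the pool labelled VEGFR2i, and 23 of 28 members were more than 1 above both bud pools in both explant pools. The corresponding medians were 2.62 and 2.10 for acinar and tip transcription factors, 1.67 and 1.66 for islet genes, 1.41 and 1.40 for endocrine progenitor genes, and 1.52 and 1.33 for epithelial genes. Endothelial genes lay below the control buds by medians of -2.42 in the pool labelled vehicle and -0.60 in the pool labelled VEGFR2i. VEGF-responsive tip cell genes were at -0.10 and 0.46, leukocyte genes at -0.36 and 0.08, and erythroid genes at -0.47 and -0.48. Culture, age, genotype and possibly normalization differ together between the sets, so these are levels and not effects.

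The last comparison set the differences of the bud pools against those of the explant pools, which share no array. By design the pairs move VEGF signalling in opposite directions, yet with the labels as they stand the genes passing the size rule in both mostly went the same way. Higher in both were 41 genes, where independent lists of these sizes would share 2.00, including Esm1, Cd34, Hba-x, Flt4, Adgrl4 and Flt1. Lower in both were 7 genes, against 0.69 for independent lists: Aldh1b1, Cbs, Cckar, Clps, Mat1a, Niban1 and Ugt2b34. Lower in the VEGF pool and higher in the pool labelled VEGFR2i were 4 genes (3.39 for independent lists), Usp17ld, Has2, Ngp and AY036118, and no gene showed the opposite pair (0.41). The counts for independent lists take all 19938 genes, including dim genes whose differences are compressed, so they may be too low. The names of the genes lower in both and of AY036118 were taken after their values were seen. Across genes, which are not independent replicates, the differences correlated with Pearson's r = 0.31 and Spearman's rho = 0.21. Without the endothelial, tip cell, mural and erythroid lists, 25 genes were higher in both and 7 lower in both, with r = 0.28 and rho = 0.20. Those lists are short, and vascular genes outside them, such as Pdgfb and Myct1, stayed among the genes higher in both. The removal therefore does not separate vascular from other shared genes.

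**Figure D3:**
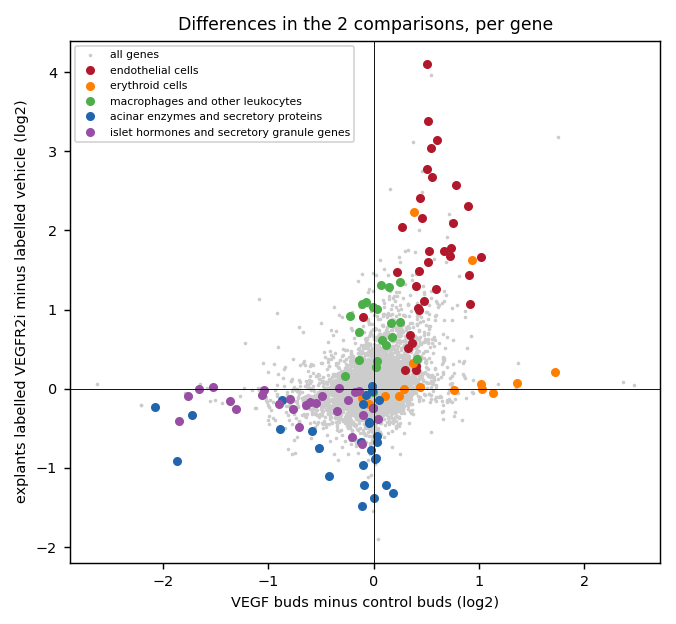
Difference in log2 expression between the VEGF and control pools (x axis) against that between the pools labelled VEGFR2i and vehicle (y axis) for each of 19938 genes, with endothelial, erythroid, leukocyte, acinar and islet lists in colour. Endothelial genes lay to the upper right, with medians of 0.51 and 1.63, and islet genes to the left, with medians of -0.62 and -0.17.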

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

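For the patterns weighed here, the tests of exchanged labels, of a faulty array, of slower endothelial loss, of more blood cells and of a lower share of epithelium were chosen only after the result was seen, while those of an endothelial gain and of liver tissue were set before.

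A set of 4 genes differed in opposite directions in the bud and explant comparisons, with all arrays of a pool on one side, and the difference between the comparisons was not tested. Usp17ld, of a large deubiquitinase family, differed by -1.09 in the VEGF pool and by 1.14 in the pool labelled VEGFR2i. Has2, a hyaluronan synthase, differed by -0.92 and 0.96. Ngp, a neutrophil granule gene near the floor in all pools, differed by -0.71 and 0.78. AY036118, which falls outside the rule for named genes, differed by -0.67 and 0.72.

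Endothelial genes were higher in the explant pool labelled VEGFR2i than in the pool labelled vehicle. A single faulty array was excluded as the cause, since the endothelial median was at least 1.55 with any 1 of the 4 arrays left out. An endothelial gain above the level of fresh buds was argued against as well. The pool labelled vehicle lay below the fresh control buds by a median of -2.42 and the pool labelled VEGFR2i at -0.60. These sets may have been normalized separately, and the values were -2.69 and -0.94 when all arrays were quantile normalized together. Culture and age differ between the sets too, so a gain over what culture alone would leave was not tested. Exchanged labels of the explant pools, under which both pools are out of place, go with 29 of 34 endothelial genes being higher. They also go with the low endothelial level of the pool labelled vehicle, though the same values gave rise to the idea. A slower loss of endothelium in culture under an acting inhibitor stays open, because the test could not decide it. The VEGF-responsive list had a median of 0.60 and a mean of 0.96, below the endothelial 1.63 and 1.69. In the VEGF pool, where VEGF was added, it also lay below the endothelial list, with medians of 0.16 against 0.51. A lower list median therefore cannot mark an acting inhibitor. Esm1, a target of VEGF, lay above the endothelial median with 3.19.

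In the VEGF pool 7 of 15 erythroid genes, the platelet gene Ppbp and 4 of 15 genes of the liver list were higher. Leukocyte genes had a median of 0.03, and 3 genes of the liver list, all bright in the control pool, were lower. More red cells and platelets in that pool are a candidate explanation: megakaryocyte and platelet genes had a median of 0.53 (percentile 100) with 6 of 12 past the size rule, although Ppbp, Pf4 and Itgb3 had been seen before, and the 9 others had a median of 0.36. Liver tissue carried along in dissection was tested with a second list of liver-secreted proteins, whose median was 0.0028 (percentile 41.7), under the bound set in advance against liver. That bound was wrong for this purpose, since 18 of the 21 members lay below the median level of all probe sets in both pools, so liver tissue remains open beside Alb (2.37), Apoa1 (0.74) and Afp (0.72). Oit3 (1.35) and Lhx9 (1.18), also among the largest increases, were on neither liver list and entered no test. A wider vascular bed filled with blood, the biological reading of the transgene, was not tested apart from blood left behind in dissection.

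In the VEGF pool 22 of 45 islet and endocrine progenitor genes were lower, and so were 10 of 26 epithelial and duct genes. A lower share of epithelium remains open: the median of all 45 was -0.55 against -0.51 for the epithelial and duct list. Some of the 45, such as Ins2 (3.37 against 3.47) and Slc30a8 (3.02 against 3.13), lay near the floor in both pools. So did Cftr of the epithelial list, at 2.98 in both. Such genes can hardly fall, so these medians cannot decide the question. The medians of the islet and endocrine progenitor lists were -0.62 and -0.36, while their means of -0.72 and -0.66 both lay below the epithelial mean of -0.42. For 9 of the 45, among them Neurog3 and Chga, every array pair lay below the lowest array pair of every epithelial and duct gene, but these are the extreme genes of the pattern and do not exclude the explanation. An earlier stage of the VEGF embryos and an effect of VEGF on endocrine differentiation were not tested against each other.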

How the results depend on the processing

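The alternatives below were planned, apart from the quantile normalization of the endothelial level against fresh buds, which was chosen after seeing the data. The counts of genes past the size rule depend on its construction: 50 genes for VEGF over control and 133 for the explants at 2-fold, 1444 and 1785 at 1.2-fold, and 522 and 670 over all probe sets. The methods' t-test after Benjamini-Hochberg adjustment left 0 and 1, against 271 and 405 unadjusted, since 2 arrays per pool leave few degrees of freedom. With the array run as a replicate block, limma gave 294 and 436. Leaving out each array in turn gave 300 to 337 genes for VEGF over control and 428 to 483 for the explants. In what follows the technical spread is narrow, so small shifts exceed it, and the cause was not tested. For VEGF over control, the endothelial median was 0.49 after quantile normalization and 0.53 after centring, its mean was 0.53, and it ranged from 0.49 to 0.51 with an array left out. The endocrine progenitor mean was -0.66 and the median ran from -0.48 to -0.34 with an array left out, and the islet mean was -0.72. Epithelial genes gave -0.54 among brighter members and a mean of -0.42, and -0.57 to -0.51 with an array left out. In the explants the endothelial mean was 1.69 and the median 1.55 to 1.64 with an array left out. Mural genes gave 0.69 after quantile normalization, 0.75 among brighter members and a mean of 0.65, and brighter members gave 0.84 for leukocyte and -0.71 for acinar genes. In the VEGF pool, the acinar median ran from -0.0905 to 0.0013 and the neural median from -0.193 to 0.0055 with an array left out, each turning positive without VEGF array 1. The genes past the size rule in the same direction in both comparisons numbered 48, against 2 at 2-fold and 439 at 1.2-fold, and those in opposite directions 4, against 1 and 70. With an array left out the first count ran from 39 to 64, and the correlation of the differences ran from 0.23 to 0.35 with an array left out. Named genes were put through quantile normalization, centring and the mean of a gene's probe sets, but not through leaving out arrays. The mean of probe sets cannot change a gene with 1 probe set. Of the 672 values from these alternatives, 668 kept their side of the size rule. The exceptions were Tagln and Acta2 in the VEGF pool, which passed after centring, Ptf1a in the explants, which passed after quantile normalization with -0.63, and Mcam in the VEGF pool, which no longer passed there with 0.57. No alternative changed the direction of the endothelial, islet or epithelial medians.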

Other observations

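Genes and lists in this part were chosen after values had been seen, and no test of a condition stands behind them.

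Some of the genes higher in the pool labelled VEGFR2i are known feedback targets of the ERK pathway. Spry4, an inhibitor of receptor tyrosine kinase signalling, differed by 1.61, the ERK phosphatase Dusp6 by 1.14, Spry2 by 0.78, the ETS factor Etv5 by 0.70, Spry1 by 0.68, Spred1 by 0.67 and Dusp5 by 0.61. They were picked from genes past the size rule, without a list or a count of all such targets, and of their relatives Dusp4 (0.54), Spred2 (0.53), Etv4 (0.48), Spry3 (0.15) and Dusp9 (-0.44) did not pass it. Of 13 genes of arterial endothelium, measured in RNA of the whole explants, 9 were higher, with a median of 1.09 (percentile 100), led by the connexins Gja5 (3.12) and Gja4 (2.49). Of 11 venous and lymphatic genes, 4 were higher, with a median of 0.51 (percentile 100). The arterial list held genes already seen, such as Gja5, Gja4 and Dll4, and the difference between the lists was not tested. In the buds 1 of 13 arterial genes was higher in the VEGF pool, with a list median of 0.38, and 2 of 11 venous and lymphatic genes, with a list median of 0.35 (both at percentile 100). In the explants the megakaryocyte list had 1 of 12 members higher and a median of -0.02 (percentile 65.3), and the second liver list had none and a median of -0.05 (percentile 22.0).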
